A study of Saccharomyces cerevisiae with 40 samples.

How the data were processed

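RNA was measured in 40 libraries of Saccharomyces cerevisiae. Per the labels' protocols, total RNA was isolated with a MasterPure yeast kit and treated with DNase I, and poly(A) RNA from 300 ng of it went into directional NEBNext Ultra II libraries. STAR 2.7.8a and Partek are named, with no role for either, per the submitters' processing notes. The genome build, the annotation and whether counting used the strand are not given in the sources used here, so no coordinates are printed. The authors deposited 1 table of normalized read counts, a signal per gene and library that is never negative. From the values, each library's estimated reads were divided by 1 factor: 88.8 to 90.9% of a library's values up to 20000 reads were whole multiples of 1 step within 0.1 read, and that step gave the estimated depths. The rest were not whole, as when a read is shared between gene models, so no count test was run. Genes with mostly fractional values (MET28, ALT2, IRC2, BNA5, IRC7, AFB1, CAR2, TRP1 and YIL082W among those named) are given as uncertain, as are near-identical copies (the PAU genes, PHO11 and PHO12). How the factors were chosen is not stated, and a factor that is off would move all genes of a library together.

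The table has 6462 genes with a symbol or systematic name and 40 columns, each matched to its sample by name. Emptied lines, 4 in all, were not used. Gene names came from the table, with 811 symbols filled in from the R64 gene table, in which 5851 names were found.

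Groups were taken from the labels. These give the letters A to D as batches, which pairs the libraries across groups. As a check, deviations from the group means correlated at a mean r of 0.174 between libraries of the same letter and -0.0576 between different letters, 29 of the 40 libraries correlated best with their own letter, and with the same-lettered Ctrl library 24 of 36 pairs had r over 0.1 (-0.0655 to 0.492). The labels do not say further how the replicates were made, so p-values measure the spread between these samples, which may be partly technical.

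Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trended prior variance, 1 mean per group over all 40 libraries, no block), for genes with a mean of at least 5, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with few reads. The comparisons were each amino acid with Ctrl, the mean of the 9 with Ctrl, each amino acid with the mean of the other 8 (genes set apart pass both this and the comparison with Ctrl in the same direction), and 5 pairs of related structure. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. Of 43 lists, 42 had at least 3 measured members. Lists chosen after seeing the data were adjusted separately from these. The test gives a list's direction against all other genes.

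The groups, comparisons, test, filter, gene lists and rule for naming genes were chosen before the data were examined, as were the alternatives unless said otherwise. Named genes in a comparison with Ctrl are the 6 largest rises and 6 largest falls past the threshold with the same sign in all 4 letters and a mean of at least 20, the amino acid's own pathway genes past the threshold (up to 6), and up to 4 past the threshold in each list described. For the mean of the 9 they are 10 each way with the same sign in all 9 groups, for genes set apart and for pairs up to 4 each way, and for shared genes up to 10 each way. PUT4 and GAP1 in Ala, GLY1 in Gly, BAT1 in Ile and HOM3 in Thr fall outside this rule and were chosen after their values were seen.

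The steps were tested on simulated data for Ala against Ctrl over 6103 genes with changes set in 200. At a log2 change of 0.58, 42 of 66 changed genes were found (63.6%), at 1, 62 of 67 (92.5%), and at 2, 63 of 67 (94.0%), with 10 false calls and none in unchanged comparisons. Alternatives were pseudocounts of 0.25 and 4, no filter, rescaling by the median of ratios or to equal totals, the letter as a block, a fit to the compared groups only, and leaving out each library. Chosen after seeing the data were the values without Phe replicate C in the results over all groups.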

Results

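The series measured messenger RNA in budding yeast, Saccharomyces cerevisiae, fed an excess of a single amino acid. The labels give 40 libraries in 10 groups of 4: a control group, here Ctrl, and 9 groups each named for the amino acid supplied, alanine (Ala), glycine (Gly), valine (Val), isoleucine (Ile), threonine (Thr), phenylalanine (Phe), tryptophan (Trp), cysteine (Cys) and methionine (Met). Within each group the libraries carry the letters A to D, which the labels call batches and which are shared across groups. The labels used here give no doses and no times of exposure, so doses may differ between amino acids. The comparisons ask what each amino acid changed against the control, what set each apart from the other 8, how amino acids of related structure differed, and which changes were common to many.

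Each library was represented by an estimated 5555852 to 17928611 reads assigned to genes (median 8736148), and the deposited normalized read counts summed to 7278922 to 9979201 per library. Of 6462 genes in the table, 6103 had a mean of at least 5 and were tested. Libraries of a group correlated across genes at r = 0.968 to 0.991 on the log2 scale over 60 pairs, and every pair differed by more than sampling noise (lowest chi-square per degree of freedom 5.59), so no library was taken for a second deposit of another. The first principal component held 23.6% of the variance and the second 12.5%. Ala lay farthest along the first (mean score 36.9 ± 7.34, SD, n = 4, against -13.3 ± 0.854 in Ctrl) and Gly farthest from Ctrl along the second (-21.1 ± 8.19 against 3.79 ± 1.41). Transcripts of HIS3, LYS2, TRP1 and ADE2, genes often deleted in laboratory strains, were present in Ctrl at 1412 ± 49.2, 12850.4 ± 1133, 434 ± 29.7 and 6112 ± 492 normalized reads. The level of TRP1 is uncertain for its shared reads, and MET17, LEU2 and URA3, of the same kind, were not analysed here. STE2, the receptor made by cells of mating type a, stood at 6989 ± 129.9 in Ctrl, and STE3, its counterpart in alpha cells, at 17.2 ± 5.92.

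Ala changed more genes than any other amino acid, 2881 of the 6103 tested (1407 up and 1474 down), followed by Gly with 1597 (855 and 742). Trp changed 752 (386 and 366), Thr 683 (358 and 325), Met 598 (370 and 228), Phe 342 (226 and 116), Val 329 (153 and 176), Cys 173 (79 and 94) and Ile 117 (77 and 40). Changes of at least 2-fold were fewer: 356 up and 177 down in Ala, 202 and 92 in Gly, 83 and 70 in Trp, 66 and 29 in Thr, 86 and 15 in Met, 83 and 13 in Phe, 33 and 24 in Val, 22 and 30 in Cys, and 26 and 8 in Ile. In at least 1 comparison 3760 genes changed, and 1934 changed in 1 comparison alone. Each call is limma's moderated test on log2(value + 1) with all 40 libraries in 1 fit and Benjamini-Hochberg adjustment. Fold changes below are on that log2 scale with their standard error, levels are means ± SD of normalized reads over 4 libraries, and the genes named for the largest rises and falls against Ctrl, or between a pair of amino acids, moved the same way in all 4 letters.

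**Figure D1:**
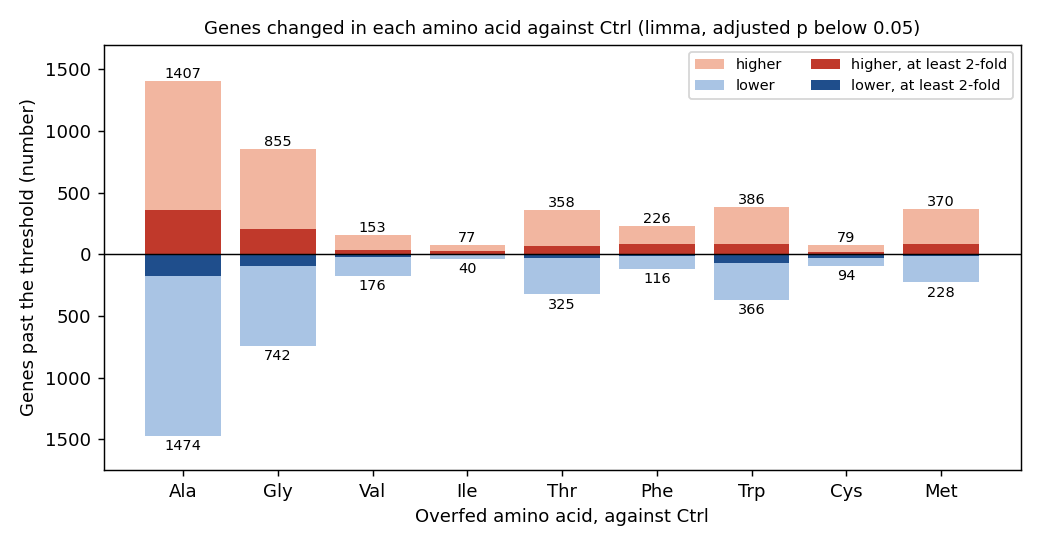
Number of genes past the threshold against Ctrl in each amino acid group, risen above the zero line and fallen below it, with the part that changed at least 2-fold shown darker. Ala (2881 genes) and Gly (1597) changed the most and Ile (117) the fewest.

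In Ala the largest rises were in genes of the cell wall that yeast expresses without oxygen. DAN1 (YJR150C), an anaerobic cell wall mannoprotein, stood at 16651 ± 5150.1 normalized reads against 3.36 ± 2.81 in Ctrl, a log2 difference of 12.05 ± 0.88 (n = 4 libraries per group, limma adjusted p = 1.69e-13). TIR1 (YER011W), of the same class, stood at 14267 ± 5268 against 53.9 ± 8.86 (7.96 ± 0.39, adjusted p = 3.98e-18). HES1 (YOR237W), an oxysterol-binding protein, rose by 6.09 ± 0.25 to 1969 ± 382. The seripauperins PAU5 (6.99 ± 0.52) and PAU24 (6.92 ± 0.66) also rose, but belong to a family of near-identical copies, and MET28 (5.82 ± 0.62), a cofactor of sulfur gene transcription, shares reads with an overlapping gene, so these 3 are uncertain. Falls were led by NDE1 (YMR145C), the external mitochondrial NADH dehydrogenase, from 3147 ± 225 to 204 ± 160.4 (-4.20 ± 0.24, adjusted p = 1.23e-16) and YKR075C (-3.42 ± 0.65). The hexose transporter HXT4 fell by 3.24, and ROX1 (YPR065W), a repressor of hypoxic genes, from 1789 ± 433 to 241 ± 51.4 (-2.88 ± 0.19, adjusted p = 1.54e-14). RGS2 (-2.74 ± 0.33) and the cytochrome oxidase assembly factor COA2 (-2.73 ± 0.28) followed. Among genes of alanine uptake and metabolism, ALT1 (YLR089C), the alanine transaminase, rose from 1653 ± 127 to 8858 ± 1646 (2.41 ± 0.13, adjusted p = 3.69e-17) and the permease DIP5 by 1.83 ± 0.29. The permease AGP1 fell by 1.04 and ALT2, which shares reads with an overlapping gene, stood at -2.05 ± 0.18. The permeases PUT4 (-0.10, adjusted p = 0.797) and GAP1 (0.07, adjusted p = 0.795) did not pass, and the list of 6 did not pass as a group. The median was -0.01, with camera adjusted p = 0.830, or adjusted p = 0.928 with an estimated correlation. Its median has the opposite sign under equal library totals, 0.17.

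Genes of the protein synthesis machinery fell in Ala. Of 137 cytosolic ribosomal proteins 1 rose, 102 fell and 34 did not pass (1 and 108 adjusted over the list alone), among them RPS22B (-1.02). The median was -0.46, with camera adjusted p = 3.23e-15, or adjusted p = 0.490 with an estimated correlation. Of 119 ribosome biogenesis factors 0 rose, 100 fell and 19 did not pass (0 and 106 adjusted over the list alone), such as DBP2 (-1.33) and NOG2 (-1.04). The median was -0.59, with camera adjusted p = 7.39e-14, or adjusted p = 0.543 with an estimated correlation. Among 34 nuclear genes of the respiratory chain and ATP synthase 0 rose, 28 fell and 6 did not pass (0 and 30 adjusted over the list alone), with COX4 at -2.35, CYC1 at -2.05 and COX5A at -1.97. The median was -0.91, with camera adjusted p = 7.39e-14, or adjusted p = 0.165 with an estimated correlation. The glycine cleavage and one-carbon genes gave 8 falls among 14 (8 adjusted over the list alone) and no rise, led by GCV2 (-1.85), GCV1 (-1.84) and SHM2 (-1.72). The median was -0.35, with camera adjusted p = 1.82e-05, or adjusted p = 0.164 with an estimated correlation. For purine biosynthesis, 1 rose, 13 fell and 2 did not pass (1 and 14 adjusted over the list alone) among 16 genes, with ADE17 at -1.14 and ADE4 at -1.06. The median was -0.72, with camera adjusted p = 1.69e-06, or adjusted p = 0.236 with an estimated correlation. Rises were gathered in the general stress response, where 32 rose, 1 fell and 29 did not pass (33 and 1 adjusted over the list alone) of 62 (HSP12 2.69, HSP26 2.55). The median was 0.83, with camera adjusted p = 2.15e-05, or adjusted p = 0.621 with an estimated correlation. They were also gathered in heat shock chaperones, where 19 rose, 0 fell and 7 did not pass (19 and 0 adjusted over the list alone) of 26 (HSP82 2.62, SSA1 1.74). The median was 0.80, with camera adjusted p = 1.72e-05, or adjusted p = 0.432 with an estimated correlation. In iron uptake 12 rose, 1 fell and 6 did not pass (12 and 1 adjusted over the list alone) of 19 (FIT2 5.20, FIT3 3.89). The median was 0.70, with camera adjusted p = 6.01e-06, or adjusted p = 0.203 with an estimated correlation. None of these list calls passed with an estimated correlation. Set against the mean of the other 8 amino acids as well as Ctrl, 2477 genes stood apart in Ala (1212 higher and 1265 lower). They included DAN1 and TIR1 above, and below them the cell wall protein CWP2, at 2585 ± 752 in Ala against 15876 ± 1436 in Ctrl and -2.97 ± 0.11 from the other groups, and CIR2 (-2.55 ± 0.08). Scaling the libraries to equal totals moved the median of all genes in Ala against Ctrl up by 0.187 and the split of changed genes to 2167 up and 758 down, and that of the genes set apart to 2043 and 560. Under it the median of the ribosomal proteins was -0.27 and that of the glycine cleavage and one-carbon genes -0.16.

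Glycine raised the genes of phosphate uptake. PHO89 (YBR296C), a sodium-coupled phosphate transporter, rose from 87.0 ± 44.4 to 4993 ± 1989 normalized reads (5.88 ± 0.36, n = 4 per group, limma adjusted p = 2.19e-15). PHO84 (YML123C), the high-affinity transporter, rose from 1714 ± 595 to 31116 ± 11267 (4.18 ± 0.26, adjusted p = 2.81e-15), and SPL2 (YHR136C), an inhibitor of low-affinity phosphate uptake, by 4.36 ± 0.38. BNA2 (YJR078W), the first enzyme of the kynurenine route from tryptophan to NAD, rose from 72.4 ± 15.1 to 909 ± 90.2 (3.65 ± 0.14, adjusted p = 8.68e-21). The stress protein HSP12 (YFL014W) rose by 4.0 ± 0.62, and MET28, uncertain for its shared reads, by 4.93 ± 0.62. The largest falls were FUS1 (YCL027W), a mating fusion protein, from 283 ± 25.5 to 49.0 ± 10.4 (-2.52 ± 0.16, adjusted p = 2.81e-15), RRT5 (-2.51 ± 0.80) and the U1 small nuclear RNA snR19 (-2.5 ± 0.45). HXT1 (YHR094C), a low-affinity glucose transporter, fell from 16919.6 ± 1214 to 3095 ± 569 (-2.47 ± 0.15), and so did YBR032W (-2.46 ± 0.49) and MFA1, which encodes the a-factor pheromone (-2.31 ± 0.49). In the list for glycine itself 7 rose, 1 fell and 3 did not pass (7 and 1 adjusted over the list alone) of 11. The glycine decarboxylase subunits GCV2, from 5626 ± 433 to 21189 ± 2744 (1.91 ± 0.13, adjusted p = 2.43e-14), GCV1 (1.78) and GCV3 (1.41) rose. The serine hydroxymethyltransferase SHM2 (1.28), MTD1 (1.26) and AGX1 (0.88) rose too, and the threonine aldolase GLY1 fell (-0.76). The median was 0.88, with camera adjusted p = 6.21e-07, or adjusted p = 0.024 with an estimated correlation. The fall of RRT5 did not pass without Ctrl replicate C (-2.11) or Gly replicate C (-2.25).

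All 7 kynurenine pathway genes rose in Gly (7 adjusted over the list alone), BNA4 by 1.78 and BNA5, with shared reads, by 1.24. The median was 0.87, with camera adjusted p = 7.94e-12, or adjusted p = 0.00278 with an estimated correlation. Likewise all 7 genes specific to mating type a fell (7 adjusted over the list alone), among them the barrier protease BAR1 (-2.23) and the receptor STE2 (-1.57). The median was -1.84, with camera adjusted p = 1.26e-12, or adjusted p = 0.00144 with an estimated correlation. Of 34 respiratory genes 25 rose, 0 fell and 9 did not pass (29 and 0 adjusted over the list alone), with CYC1 at 1.46 and INH1 at 1.06. The median was 0.52, with camera adjusted p = 1.06e-10, or adjusted p = 0.228 with an estimated correlation. Of 35 sulfur assimilation and methionine genes 17 rose, 0 fell and 18 did not pass (19 and 0 adjusted over the list alone), such as STR3 (3.08) and MET6 (1.62). The median was 0.50, with camera adjusted p = 1.18e-08, or adjusted p = 0.111 with an estimated correlation. In the general stress list 29 rose, 0 fell and 33 did not pass (33 and 0 adjusted over the list alone) of 62. The median was 0.80, with camera adjusted p = 2.78e-08, or adjusted p = 0.543 with an estimated correlation. Its libraries differed: the mean log2 level was 8.68, 7.72, 9.56 and 8.12 in replicates A to D of Gly, against 7.43 to 7.57 in Ctrl. Ribosome biogenesis factors gave 28 falls among 119 (27 adjusted over the list alone). The median was -0.34, with camera adjusted p = 1.52e-09, or adjusted p = 0.609 with an estimated correlation. The permeases induced by external amino acids gave 5 falls among 8 (5 adjusted over the list alone; PTR2 -1.73, AGP1 -1.05). The median was -0.44, with camera adjusted p = 0.0021, or adjusted p = 0.236 with an estimated correlation. Against the mean of the other 8 amino acids and Ctrl, 1055 genes stood apart in Gly (601 higher, 454 lower). CHA1 (YCL064C), the serine and threonine deaminase, was at 1263 ± 222 in Gly and 3.31 ± 0.13 above the other groups (adjusted p = 2.25e-21), and DPA10 was 3.21 ± 0.49 above. On the lower side were FUS1 (-2.69 ± 0.12), the hypoxic translation factor ANB1 (-2.64 ± 0.23) and the cell wall protein TIP1 (-2.40 ± 0.15).

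Valine raised CIT2 (YCR005C), the peroxisomal citrate synthase, from 1162 ± 572 to 5171 ± 1242 normalized reads (2.25 ± 0.32, n = 4 per group, limma adjusted p = 1.21e-05). DPI8 rose from 200 ± 64.1 to 839 ± 262 (2.05 ± 0.33) and SPO24 by 1.83 ± 0.34. SPL2 rose by 1.82 ± 0.38, the acid phosphatase PHO12, which has a near-identical copy, by 1.93 ± 0.21, and MET28 by 3.73 ± 0.62; the last 2 are uncertain. Falls were led by HXT4 (-2.63 ± 0.38) and by the vitamin B6 synthesis pair SNZ1 (YMR096W), from 5251 ± 567 to 1111 ± 116 (-2.24 ± 0.17, adjusted p = 2.27e-11), and SNO1 (-1.96 ± 0.15). Then came the hexose transporter HXT2 (-1.71 ± 0.36), STP4 (-1.62 ± 0.37) and ARO5 (-1.58 ± 0.29). In the list of valine synthesis, transport and breakdown 1 rose, 1 fell and 9 did not pass (1 and 2 adjusted over the list alone) of 11. ILV6 (YCL009C), the regulatory subunit of acetolactate synthase, fell from 11473 ± 982 to 7414 ± 456 (-0.63 ± 0.12, adjusted p = 7.86e-04). BAT2 (YJR148W), the cytosolic branched-chain aminotransferase, rose from 1464 ± 62.3 to 2161 ± 243 (0.56 ± 0.13, adjusted p = 0.00666). The median was -0.08, with camera adjusted p = 0.704, or adjusted p = 0.911 with an estimated correlation.

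Of 13 aromatic amino acid synthesis genes in Val 0 rose, 7 fell and 6 did not pass (0 and 10 adjusted over the list alone), with ARO3 at -0.86 and ARO4 at -0.70. The median was -0.44, with camera adjusted p = 4.51e-09, or adjusted p = 0.0517 with an estimated correlation. In histidine synthesis 3 of 6 fell and none rose (5 adjusted over the list alone; HIS4 -1.0, HIS5 -0.79). The median was -0.50, with camera adjusted p = 4.16e-06, or adjusted p = 0.0904 with an estimated correlation. In sulfur assimilation 14 rose, 1 fell and 20 did not pass (17 and 3 adjusted over the list alone) of 35, led upward by SEO1 (1.41), MHT1 (1.35) and SAM2 (1.22). The median was 0.37, with camera adjusted p = 2.01e-07, or adjusted p = 0.164 with an estimated correlation. Among genes under nitrogen catabolite repression 8 rose, 0 fell and 17 did not pass (14 and 2 adjusted over the list alone) of 25, such as the ammonium permease MEP2 (1.40) and the general permease GAP1 (1.16). The median was 0.47, with camera adjusted p = 4.82e-07, or adjusted p = 0.0798 with an estimated correlation. By the comparison with the mean of the other 8 amino acids and with Ctrl, 113 genes stood apart in Val (40 higher, 73 lower). They held MEP2 (1.01 ± 0.15) and LEU1 (YGL009C) of leucine synthesis, at 22148 ± 1719 (1.0 ± 0.10), on the higher side, and SNZ1 (-1.81 ± 0.13) and ARO5 (-1.80 ± 0.21) on the lower. With the letters as a block 499 genes changed in Val against Ctrl and 177 stood apart, and the fit to the Val and Ctrl libraries alone called 494. Leaving out 1 library lowered the 329 to 217 (Ctrl replicate A), 204 (Ctrl D), 219 (Val A) or 207 (Val C), and the 113 to 63 (Val A) or 65 (Val C). With equal library totals the split against Ctrl was 114 up and 283 down, and 26 and 149 among 175 genes set apart.

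In Ile CIT2, DPI8, SPO24, SNZ1, SNO1 and HXT4 were again among the leading genes. CIT2 rose to 3879 ± 1016 normalized reads (1.82 ± 0.32, n = 4 per group, limma adjusted p = 4.41e-04), DPI8 by 1.76 ± 0.33, SPO24 by 1.51 ± 0.34, and MET28, uncertain, by 3.41 ± 0.62. MHT1 (YLL062C), a methyltransferase that makes methionine from homocysteine, rose from 28.2 ± 6.21 to 88.8 ± 14.1 (1.63 ± 0.26) and the cystathionine lyase STR3 by 1.51 ± 0.33. SNZ1 fell to 1228 ± 241 (-2.11 ± 0.17, adjusted p = 1.25e-10), SNO1 by 1.82, HXT4 by 1.77, YOL118C by 1.08, and ARG7 (YMR062C) of arginine synthesis from 4379 ± 760.3 to 1848 ± 119 (-1.23 ± 0.18). The transposon gene YIL082W (-1.42), which shares reads with its copies, is uncertain. In isoleucine synthesis and use 0 rose, 3 fell and 9 did not pass (2 and 8 adjusted over the list alone) of 12. The falls were ILV6 (-0.60 ± 0.12, adjusted p = 0.00265), ILV3 (-0.52, adjusted p = 0.0221) and ILV2 (-0.34, adjusted p = 0.0477). The mitochondrial aminotransferase BAT1 stood at -0.59 (adjusted p = 0.0599). The median was -0.34, with camera adjusted p = 2.01e-05, or adjusted p = 0.186 with an estimated correlation. Some of these calls were lost when 1 library was left out. ILV3 did not pass without Ctrl A (-0.53), B (-0.51), D (-0.51) or Ile D (-0.43). YIL082W did not without Ctrl A (-1.24), C (-1.5), D (-1.29), Ile B (-0.87) or C (-1.55) or in the fit to these libraries alone, nor ILV2 without any 1 library but Ctrl C (-0.35 to -0.32).

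Across branched-chain amino acid biosynthesis in Ile 0 rose, 5 fell and 6 did not pass (0 and 9 adjusted over the list alone) of 11, with LEU4 at -0.90 and LEU9 at -0.43. The median was -0.43, with camera adjusted p = 5.01e-13, or adjusted p = 0.0454 with an estimated correlation. With the letters as a block the latter p was 0.0537. Of 35 sulfur assimilation genes 17 rose, 1 fell and 17 did not pass (17 and 1 adjusted over the list alone), such as SEO1 (1.39), SAM2 (1.22) and MET3 (1.15). The median was 0.26, with camera adjusted p = 8.47e-17, or adjusted p = 0.024 with an estimated correlation. This p too was 0.0537 with the block. Aromatic synthesis gave 3 falls among 13 (10 adjusted over the list alone). The median was -0.36, with camera adjusted p = 9.26e-10, or adjusted p = 0.0517 with an estimated correlation. Histidine synthesis gave 2 among 6 (4 adjusted over the list alone). The median was -0.43, with camera adjusted p = 1.23e-07, or adjusted p = 0.0526 with an estimated correlation. In Ile 54 genes stood apart from the mean of the other 8 amino acids and from Ctrl (26 higher, 28 lower). Among them were the mating agglutinin AGA1 (1.01 ± 0.20), SER3 of serine synthesis (0.97 ± 0.16), SNZ1 (-1.67 ± 0.13) and SNO1 (-1.52 ± 0.11). Without Ile replicate A the count was 33. Equal library totals gave 68 up and 58 down against Ctrl, and 25 higher and 41 lower among genes set apart.

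Threonine, like glycine, raised phosphate genes. SPL2 rose by 3.40 ± 0.38 (n = 4 per group, limma adjusted p = 2.90e-08), PHO89 to 758 ± 214 normalized reads (3.22 ± 0.36) and PHO84 to 13476 ± 1532 (3.04 ± 0.26). The near-identical acid phosphatases PHO12, to 609 ± 25.6 (3.13 ± 0.21, adjusted p = 4.08e-13), and PHO11, to 208 ± 17.4 (2.96 ± 0.20), rose too, but their reads cannot be assigned with certainty. MET28, uncertain, rose by 3.33 ± 0.62. Falls were led by YKR075C (-2.75 ± 0.65), ANB1, from 76.4 ± 33.6 to 22.2 ± 4.67 (-1.68 ± 0.31), and HXT2 (-1.67 ± 0.36). IMD2 (YHR216W), an IMP dehydrogenase of guanine nucleotide synthesis, fell from 1268 ± 227 to 396 ± 37.7 (-1.66 ± 0.19), followed by MIG2, a repressor active in glucose (-1.57 ± 0.34), and snR19 (-1.52 ± 0.45). Of 11 genes of threonine synthesis and breakdown 1 rose, 4 fell and 6 did not pass (1 and 5 adjusted over the list alone). CHA1, which degrades threonine, rose from 106 ± 14.7 to 414 ± 56.2 (1.95 ± 0.17, adjusted p = 7.30e-11). GLY1 (-0.73), HOM2 (-0.55), AAT2 (-0.46) and ILV1 (-0.34) fell, and HOM3, the first enzyme of the branch, stood at -0.43 (adjusted p = 0.0992). The median was -0.28, with camera adjusted p = 0.043, or adjusted p = 0.565 with an estimated correlation. Without 1 library snR19 (Ctrl A -1.36, Ctrl B -1.47, Thr C -1.48, Thr D -1.15) and ILV1 (Ctrl B -0.34, Ctrl C -0.31, Thr C -0.29, Thr D -0.34) did not pass.

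In branched-chain biosynthesis 0 rose, 10 fell and 1 did not pass (0 and 10 adjusted over the list alone) of 11 in Thr, the oxaloacetate transporter OAC1 at -1.37, LEU1 at -1.31 and BAT1 at -1.14. The median was -0.61, with camera adjusted p = 9.25e-12, or adjusted p = 0.0517 with an estimated correlation. The mating type a genes gave 6 falls among 7 (6 adjusted over the list alone), with BAR1 at -0.93 and STE2 at -0.75. The median was -0.75, with camera adjusted p = 3.85e-08, or adjusted p = 0.015 with an estimated correlation. Sulfur assimilation showed the opposite direction, 11 rose, 0 fell and 24 did not pass (12 and 0 adjusted over the list alone) of 35 (SAM2 1.53, STR3 1.51). The median was 0.24, with camera adjusted p = 5.16e-06, or adjusted p = 0.203 with an estimated correlation. In Thr 351 genes stood apart from the mean of the other 8 amino acids and from Ctrl (210 higher, 141 lower). The zinc transporter ZRT1 (YGL255W), at 4229.6 ± 375 (2.01 ± 0.30), and the mating type switching endonuclease HO (YDL227C), at 4320.2 ± 310.0 against 1062 ± 104 in Ctrl (2.01 ± 0.12), were higher. ZRT1 was higher still in the Cys libraries, at 6751 to 16233. ANB1 (-2.39 ± 0.23), IMD2 (-2.02 ± 0.14) and LEU1, at 4655 ± 198 (-1.53 ± 0.10), were lower.

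Phenylalanine raised ARO9 and ARO10, which act in the breakdown of aromatic amino acids to fusel alcohols. ARO9 (YHR137W), the aromatic aminotransferase, stood at 11038 ± 3122 normalized reads against 45.8 ± 12.8 in Ctrl (7.88 ± 0.31, n = 4 per group, limma adjusted p = 8.34e-21). ARO10 (YDR380W), the phenylpyruvate decarboxylase, stood at 13659.9 ± 3525 against 128 ± 15.7 (6.71 ± 0.21, adjusted p = 1.04e-23). MET28, uncertain, rose by 5.61 ± 0.62, SPL2 by 3.51 ± 0.38, PHO89 by 3.30 ± 0.36 and PHO84 to 13826 ± 615 (3.08 ± 0.26). Falls were smaller: YHR138C (-1.75 ± 0.30), YLR297W (-1.57 ± 0.32) and HXT4 (-1.54 ± 0.38). So were those of the peptide transporter PTR2 (-1.35 ± 0.15), the mitochondrial oxodicarboxylate carrier ODC2, from 2679.5 ± 131 to 1118 ± 168 (-1.27 ± 0.13), and the transposon gene YIL082W (-1.46), uncertain for its copies. In the list of phenylalanine synthesis and use 2 rose, 1 fell and 12 did not pass (5 and 3 adjusted over the list alone) of 15, the fall being ARO4, which opens aromatic synthesis (-0.45 ± 0.11, adjusted p = 0.00972). The median was 0.10, with camera adjusted p = 0.00606, or adjusted p = 0.177 with an estimated correlation. Calls that did not pass without 1 library were HXT4 (Ctrl A, -1.34), ARO4 (Phe C, -0.38) and YIL082W (Ctrl A -1.28, Ctrl D -1.33, Phe B -1.28, Phe D -1.32), the last also in the fit to these libraries alone.

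Of 13 genes of the Ehrlich pathway and targets of its activator Aro80 in Phe 4 rose, 1 fell and 8 did not pass (6 and 2 adjusted over the list alone), with ESBP6 at 1.95 and BAT2 at 1.01 beside ARO9 and ARO10. The median was 0.50, with camera adjusted p = 5.58e-09, or adjusted p = 6.64e-04 with an estimated correlation. In sulfur assimilation 14 rose, 1 fell and 20 did not pass (22 and 2 adjusted over the list alone) of 35, such as MET16 (1.95), STR3 (1.88) and the sulfate permease SUL1 (1.87). The median was 0.49, with camera adjusted p = 8.17e-19, or adjusted p = 0.015 with an estimated correlation. Among branched-chain biosynthesis genes 7 rose, 1 fell and 3 did not pass (8 and 1 adjusted over the list alone) of 11, LEU1 by 2.01 and OAC1 by 1.67. The median was 0.53, with camera adjusted p = 9.37e-09, or adjusted p = 0.0887 with an estimated correlation. Lysine synthesis gave 6 falls among 9 (6 adjusted over the list alone), LYS9 at -0.60 and LYS1 at -0.58. The median was -0.45, with camera adjusted p = 1.10e-06, or adjusted p = 0.098 with an estimated correlation. The general stress list did not pass, with 1 rise and 0 falls (1 and 0 adjusted over the list alone). The median was 0.10, with camera adjusted p = 0.232, or adjusted p = 0.910 with an estimated correlation. Replicate C stood apart in it, with a mean log2 level of 9.15 against 7.04 to 7.47 in the other 3 Phe libraries and 7.43 to 7.57 in Ctrl. In Phe 162 genes stood apart from the mean of the other 8 amino acids and from Ctrl (111 higher, 51 lower). ARO9 (6.0 ± 0.23), ARO10 (5.59 ± 0.16), SRL4 (2.38 ± 0.31) and LEU1, at 46750.5 ± 5442 (2.21 ± 0.10), were higher. YHR138C (-1.59 ± 0.22) and the siderophore transporter ENB1 (-1.03 ± 0.11) were lower. ARO9 and ARO10 were high in Trp as well, so they set Phe apart from the mean of the others only. Without Phe replicate B, 102 genes stood apart. The fit to the Phe and Ctrl libraries alone called 195 genes in place of 342.

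Tryptophan raised ARO9 and ARO10 too. ARO9 reached 18240.5 ± 1451 normalized reads against 45.8 ± 12.8 in Ctrl (8.64 ± 0.31, n = 4 per group, limma adjusted p = 3.82e-22) and ARO10 19200.5 ± 1957 against 128 ± 15.7 (7.23 ± 0.21, adjusted p = 8.24e-25). Phosphate genes rose as well, SPL2 by 4.08 ± 0.38, PHO84 to 20212 ± 3294 (3.62 ± 0.26) and PHO12, uncertain for its copy, by 4.12 ± 0.21, and DAN1 stood at 73.6 ± 45.4 (3.82 ± 0.88, adjusted p = 0.0032). SNZ1 had the largest fall, to 603 ± 56.2 (-3.12 ± 0.17, adjusted p = 3.78e-16), followed by BSC1 (-2.62 ± 0.65), snR19 (-2.60 ± 0.45), HXT4 (-2.58 ± 0.38), PRM7 (-2.48 ± 0.65) and YKR075C (-2.45 ± 0.65). In the list of tryptophan synthesis and breakdown 5 rose, 4 fell and 6 did not pass (5 and 6 adjusted over the list alone) of 15. BNA2 rose by 0.92 ± 0.14 (adjusted p = 1.63e-05) and BNA5, uncertain for shared reads, by 0.79, while ARO3 (-0.86) and ARO4 (-0.69), which open aromatic synthesis, fell. The list did not pass as a group, its median being -0.21 and its mean 0.97 (camera adjusted p = 0.187, adjusted p = 0.609 with an estimated correlation). PRM7 did not pass without Trp replicate A (-2.16) or D (-2.12), nor YKR075C without Trp D (-2.02).

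Of 13 Ehrlich pathway genes in Trp 5 rose, 1 fell and 7 did not pass (5 and 2 adjusted over the list alone), with ESBP6 at 2.25 and the activator ARO80 at 1.31, and the weak acid pump PDR12 at -1.37. The median was 0.16, with camera adjusted p = 3.36e-06, or adjusted p = 0.00431 with an estimated correlation. Kynurenine genes gave 4 rises among 7 (4 adjusted over the list alone). The median was 0.48, with camera adjusted p = 1.08e-05, or adjusted p = 0.0517 with an estimated correlation. In iron uptake 8 rose, 0 fell and 11 did not pass (8 and 0 adjusted over the list alone) of 19, such as FIT2 (2.47) and SIT1 (1.21). The median was 0.27, with camera adjusted p = 1.88e-04, or adjusted p = 0.303 with an estimated correlation. Respiratory genes fell in 15 of 34 cases (22 adjusted over the list alone) and rose in 0, NDE1 at -1.19 and CYC1 at -0.95. The median was -0.41, with camera adjusted p = 9.26e-10, or adjusted p = 0.236 with an estimated correlation. In Trp 295 genes stood apart from the mean of the other 8 amino acids and from Ctrl (154 higher, 141 lower). These were led by ARO9 (6.86 ± 0.23), ARO10 (6.18 ± 0.16) and SDH6 (2.53 ± 0.21) on the higher side, and by SNZ1 (-2.80 ± 0.13), ZRT1, at 263 ± 42.0 (-2.5 ± 0.30), and SNO1 (-1.98 ± 0.11) on the lower. Against Ctrl 1311 genes were called by the fit to those libraries alone, and 465 without Trp replicate A or 481 without D, in place of 752. The 295 became 160 without Trp A, 193 without Trp B and 142 without Trp D, and split into 114 higher and 169 lower with equal library totals.

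Cysteine gave its largest rise in ZRT1 (YGL255W), the high-affinity zinc transporter, from 1016 ± 429 to 12101 ± 3998 normalized reads (3.58 ± 0.40, n = 4 per group, limma adjusted p = 9.57e-08). RIB4 (YOL143C) of riboflavin synthesis rose from 939 ± 248 to 4459.8 ± 488 (2.27 ± 0.16, adjusted p = 5.90e-13). The arginine synthesis enzymes ARG8 (1.84 ± 0.17) and ARG3 (1.5 ± 0.30) rose, and URA1 (YKL216W) of pyrimidine synthesis rose from 3829 ± 1238 to 11329 ± 1004 (1.61 ± 0.19). AFB1 (1.48) and CAR2 (-2.03) share reads with overlapping genes and are uncertain. Phosphate genes fell, SPL2 from 27.5 ± 7.34 to 5.11 ± 3.64 (-2.59 ± 0.38) and PHO89 from 87.0 ± 44.4 to 15 ± 6.61 (-2.37 ± 0.36). LEU1 fell from 11554 ± 906 to 2784 ± 238 (-2.05 ± 0.14, adjusted p = 5.64e-13), as did ARO9 (-1.81 ± 0.31) and HXT2 (-1.68 ± 0.36). In the list of cysteine synthesis and use 1 rose, 2 fell and 8 did not pass (1 and 3 adjusted over the list alone) of 11. These were IRC7, a cysteine desulfhydrase with shared reads, at 0.69 (adjusted p = 0.0377), the methionine permease MUP1 at -0.58 (adjusted p = 0.0382) and GSH2 of glutathione synthesis at -0.40 (adjusted p = 0.0433). The median was -0.13, with camera adjusted p = 0.225, or adjusted p = 0.574 with an estimated correlation. None of these 3 held throughout. IRC7 did not pass without Ctrl A (0.66), B (0.63) or D (0.64) or Cys A (0.66), B (0.66) or C (0.66). MUP1 did not without Ctrl B (-0.60), C (-0.58) or D (-0.49) or Cys A (-0.37), B (-0.59) or C (-0.60), nor GSH2 without Ctrl A (-0.36), B (-0.37) or D (-0.42) or Cys A (-0.40), B (-0.36) or C (-0.38). MUP1 and GSH2 also did not in the fit to these libraries alone.

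Branched-chain synthesis in Cys gave 5 falls among 11, and 3 rises with 8 falls adjusted over the list alone, OAC1 at -1.37 and BAT1 at -1.09. The median was -0.54, with camera adjusted p = 3.31e-08, or adjusted p = 0.098 with an estimated correlation. Of 10 arginine synthesis genes 5 rose, 0 fell and 5 did not pass (5 and 0 adjusted over the list alone). The median was 0.49, with camera adjusted p = 3.56e-07, or adjusted p = 0.248 with an estimated correlation. Zinc uptake gave 3 rises among 11 (3 adjusted over the list alone), including the activator ZAP1 (0.64). The median was 0.11, with camera adjusted p = 8.12e-04, or adjusted p = 0.239 with an estimated correlation. In sulfur assimilation 0 rose, 4 fell and 31 did not pass (0 and 6 adjusted over the list alone) of 35, MMP1 at -1.14. The median was -0.13, with camera adjusted p = 2.63e-04, or adjusted p = 0.327 with an estimated correlation. No member of the general stress list passed among 62, while the list as a group lay lower (0 rises and 0 falls adjusted over the list alone). The median was -0.38, with camera adjusted p = 1.08e-05, or adjusted p = 0.609 with an estimated correlation. In Cys 144 genes stood apart from the mean of the other 8 amino acids and from Ctrl (57 higher, 87 lower). ZRT1 (3.64 ± 0.30) and SNO1 (1.37 ± 0.11) were higher, and SPL2 (-5.15 ± 0.28), ARO9 (-4.91 ± 0.23), PHO89 (-4.75 ± 0.27) and PHO84, at 550.0 ± 109 (-3.86 ± 0.19), lower. The fit to the Cys and Ctrl libraries alone called 79 genes in place of 173, without SPL2, ARG3 or ARO9 among them. Leaving out Ctrl replicate A or Cys B gave 103 and 108 against Ctrl and 88 and 86 set apart, and without Ctrl B 93 stood apart. With equal totals 55 genes were up and 146 down, and 39 higher and 135 lower among those set apart. The zinc and sulfur medians were then 0.05 and -0.20.

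Methionine raised ATG41 (YPL250C), an autophagy protein, from 105 ± 26.9 to 927 ± 201 normalized reads (3.13 ± 0.34, n = 4 per group, limma adjusted p = 2.52e-08). PHO89 rose to 634 ± 78.9 (3.0 ± 0.36), SPO24 by 2.7 ± 0.34 and ARO9 to 292 ± 72.7 (2.65 ± 0.31). FIT2 (YOR382W), a cell wall protein that binds siderophore iron, rose from 113 ± 30.6 to 657 ± 172 (2.54 ± 0.28), and MET28, uncertain, by 2.84 ± 0.62. The largest falls were YGR035C (-1.73 ± 0.38), YBR032W (-1.55 ± 0.49), PDR12 (YPL058C), a weak acid efflux pump, from 2506 ± 327 to 943 ± 144 (-1.41 ± 0.25), and YBR238C (-1.27 ± 0.32). ALT2 (-1.27) and IRC2 (-1.45), which overlap each other and share reads, are uncertain. In methionine synthesis, transport and use 2 rose, 2 fell and 11 did not pass (4 and 3 adjusted over the list alone) of 15. MET16 of sulfate reduction rose by 0.71 ± 0.19 (adjusted p = 0.0142). The S-adenosylmethionine synthetases SAM2 (YDR502C), from 1807 ± 451 to 1118 ± 255 (-0.69 ± 0.13, adjusted p = 4.38e-04), and SAM1 (-0.49 ± 0.16, adjusted p = 0.0485) fell. The list did not pass as a group, with a median of -0.10 and a mean of 0.12 (camera adjusted p = 0.923, adjusted p = 0.972 with an estimated correlation). Without 1 library YBR032W (Ctrl A -1.56, Ctrl B -1.47, Ctrl C -1.58, Ctrl D -1.60, Met B -1.26, Met D -1.36), MET16 (Ctrl D 0.61, Met C 0.52) and SAM1 (any but Met C, -0.54 to -0.34) did not pass. Nor did MET16 and SAM1 in the fit to these libraries alone or SAM1 without the filter on low values.

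Of 19 iron uptake genes 13 rose, 0 fell and 6 did not pass (14 and 0 adjusted over the list alone) in Met, among them TIS11 (1.53), which binds messenger RNAs of iron-using proteins, and HMX1 (1.07), a heme oxygenase. The median was 0.68, with camera adjusted p = 1.92e-12, or adjusted p = 0.0517 with an estimated correlation. Branched-chain synthesis gave 6 rises among 11 (7 adjusted over the list alone), BAT2 at 1.91 and LEU1 at 0.89. The median was 0.51, with camera adjusted p = 1.09e-07, or adjusted p = 0.111 with an estimated correlation. In the Ehrlich list 6 rose, 1 fell and 6 did not pass (7 and 2 adjusted over the list alone) of 13, such as ADH5 (1.19) and ARO10 (0.91). The median was 0.36, with camera adjusted p = 0.00159, or adjusted p = 0.0517 with an estimated correlation. In Met 334 genes stood apart from the mean of the other 8 amino acids and from Ctrl (232 higher, 102 lower). SNZ1, at 11934 ± 1376 (2.04 ± 0.13), ARO5 (1.91 ± 0.21), YCR102C (2.02 ± 0.10) and YLR460C (1.80 ± 0.08) were higher. SAM2, at 1118 ± 255 (-1.66 ± 0.10), MEP2 (-1.36 ± 0.15) and GAP1 (-1.32 ± 0.15) were lower. With equal library totals 483 genes were up and 134 down against Ctrl, and 324 higher and 69 lower among those set apart.

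Valine and isoleucine, whose branched side chains differ by a methylene group, changed 8 genes differently (1 higher and 7 lower in Ile by limma, and 261 at an unadjusted p under 0.05). BAT2 stood at 1077 ± 69.8 in Ile and 2161 ± 243 in Val (log2 difference -1.0 ± 0.13, adjusted p = 3.52e-05), LEU1 at 11553 ± 3122 and 22148 ± 1719 (-0.98 ± 0.14). The near-identical phosphatases PHO11 (-1.12 ± 0.20) and PHO12 (-1.09 ± 0.21) were also lower in Ile, and PTR2 was higher (0.74 ± 0.15, adjusted p = 0.0204). For 5617 of 6103 genes (92.0%) the 95% interval of the difference lay within 2-fold, and the median interval reached 0.272 to either side. PHO12 did not pass without Ile B (-1.02), Ile C (-1.05) or Val B (-1.05). PTR2 did not without Ile A (0.76), B (0.69) or D (0.64) or Val A (0.73), B (0.74) or D (0.73). The count was 5 without Ile D and 13 in the fit to these libraries alone. Threonine and valine have side chains of like shape with a hydroxyl in place of a methyl group. They differed in 400 genes (227 higher and 173 lower in Thr), with intervals within 2-fold for 5434 (89.0%). CHA1 (2.13 ± 0.17), SNZ1 (1.96 ± 0.17), PHO89 (1.90 ± 0.36) and ZRT1 (1.85 ± 0.40) were higher in Thr. LEU1, at 4655 ± 198 against 22148 ± 1719 (-2.25 ± 0.14), OAC1 (-1.97 ± 0.14) and SER3 (-1.80 ± 0.21) were lower. With equal totals the split was 324 and 117.

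Phenylalanine and tryptophan, with phenyl and indole side chains, shared the rise of ARO9 and ARO10 and differed in 726 genes (358 higher and 368 lower in Phe). SNZ1 stood at 4039 ± 1258 in Phe and 603 ± 56.2 in Trp (2.69 ± 0.17), SRL4 at 2.88 ± 0.41 and PHO89 at 2.27 ± 0.36. Lower in Phe were DAN1 (-3.53 ± 0.88), TIR1 (-2.34 ± 0.39), TIS11, at 50.6 ± 8.88 against 199 ± 25.5 (-1.96 ± 0.28), and FIT2 (-1.91 ± 0.28). ARO9 differed between them by -0.76 ± 0.31 (adjusted p = 0.0983) and ARO10 by -0.52 ± 0.21 (adjusted p = 0.0983), neither past the threshold, these 2 being named after their values were seen. Intervals lay within 2-fold for 5350 genes (87.7%). This count moved most with single libraries: it was 1389 without Phe replicate C, 478 without Phe A, 352 without Phe B, 414 without Phe D, 469 without Trp A and 405 without Trp D, and 269 in the fit to these libraries alone. With equal totals it split into 440 and 226.

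Alanine and glycine, with methyl and hydrogen side chains, differed in 1882 genes (952 higher and 930 lower in Ala). ANB1 stood at 4007 ± 1312 in Ala and 18.7 ± 0.869 in Gly (7.61 ± 0.31), TIR1 was higher in Ala by 7.90 ± 0.39 and DAN1 by 12.91 ± 0.88. PHO89 (-5.87 ± 0.36), SPL2 (-4.17 ± 0.38), NDE1 (-4.11 ± 0.24) and COA2 (-4.06 ± 0.28) were lower. Intervals lay within 2-fold for 4952 genes (81.1%), the fit to these libraries alone called 1199, and equal totals shifted the median by 0.190 and the split to 1945 and 451. Methionine, a thioether, and cysteine, a thiol, differed in 1624 genes (815 higher and 809 lower in Met), with intervals within 2-fold for 5126 (84.0%). PHO89 (5.38 ± 0.36), SPL2 (5.04 ± 0.38), ARO9 (4.46 ± 0.31) and CPP3 (3.67 ± 0.82) were higher in Met. ZRT1 (-3.10 ± 0.40), PRM7 (-2.39 ± 0.65) and BSC1 (-2.31 ± 0.65) were lower. This count was 976 in the fit to these libraries alone and 1050 without Cys replicate B, and equal totals shifted the median by 0.140 and the split to 1385 and 325.

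Averaged over the 9 amino acids, 551 genes differed from Ctrl (314 up and 237 down). Among genes with a higher mean than Ctrl in all 9 groups, the rises were led by MET28 (3.67 ± 0.47, uncertain), HSP12 (2.06 ± 0.46, limma adjusted p = 0.00275), SPO24 (1.85 ± 0.25), ATG41 (1.68 ± 0.25), and CIT2 (1.65 ± 0.24, adjusted p = 6.43e-06). Next were DPI8 (1.60 ± 0.24), FIT2 (1.49 ± 0.21), the cell wall protein CWP1 (1.43 ± 0.28), RIB4 (1.31 ± 0.12, adjusted p = 3.61e-10) and YPR078C (1.28 ± 0.22). The falls were led by YKR075C (-1.93 ± 0.49), HXT4 (-1.66 ± 0.28, adjusted p = 9.28e-05), the small RNAs snR19 (-1.59), snR42 (-1.38) and snR30 (-1.13), HAP4, an activator of respiratory genes (-1.35 ± 0.24), HXT2 (-1.34 ± 0.27), STP4 (-1.23 ± 0.28), RGS2 (-1.15 ± 0.24) and MIG2 (-1.12 ± 0.25). The libraries were made from poly(A) RNA, so levels of the small RNAs, which mostly lack a poly(A) tail, are uncertain. YKR075C did not pass without Ctrl replicate A (-1.75) or B (-1.81), snR42 without Ctrl A (-1.30), B (-1.36) or D (-1.27), and snR30 without any 1 Ctrl library (-1.26 to -1.01). Without Ctrl A, B or D the count was 341, 319 or 336.

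In at least 5 of the 9 comparisons 224 genes changed the same way (135 up and 89 down). DPI8 rose in all 9, by 1.29 in Cys to 2.05 in Val, and so did DAL2, an allantoicase of nitrogen scavenging, by 0.38 to 1.0. CIT2, PHO12, SPO24, RIB4, BNA2, RTS3, the transcription factor ADR1 and MET28 rose in 8. The glycolytic regulator PFK27 fell in 7 (-1.51 in Val, with -0.32 in Cys), as did the glucose transporter HXT1 (-2.47 in Gly, with -0.14 in Cys), CTP1, the mitotic cyclin CLB2, the replication helicase subunit MCM7, YCR024C-B and RPL9B. The 9 comparisons share the Ctrl libraries. With every library simulated as noise around the Ctrl means without effects, the mean count was 0 and the highest of 100 simulations 0. Noise alone passes the adjusted threshold in few genes, so this cannot show what the shared libraries add. Independent lists of the same sizes give 0.602. With alternate comparisons given different Ctrl libraries, fewer for each, the count was 81 or 98. There 5 of the 9 comparisons still shared their Ctrl libraries, so the sharing was not removed. Leaving out Ctrl replicate A lowered the 224 to 148. Across genes, which are not independent replicates, the log2 fold changes of 2 amino acids correlated with a median r of 0.455 over the 36 pairs, from -0.0141 (Met and Cys) to 0.744 (Ile and Val), against 0.501 simulated with no effect. The median covariance was 0.0657 against 0.0247 simulated, a difference of 0.0410. With the controls split between the 2 amino acids of each pair, r was 0.287 and the covariance 0.0456. With the letters also removed they were 0.324 and 0.0505.

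Over 42 gene lists and 9 comparisons, 178 of 378 pairs passed the camera test with its preset correlation, 97 higher and 81 lower, and 10 passed with an estimated correlation. Those 10 were the kynurenine, mating type a and glycine lists in Gly, the mating type a list in Thr, the Ehrlich list in Phe and Trp, the sulfur list in Phe and Ile, and in Ile the branched-chain list and the list for methionine. In the last of these 8 rose, 1 fell and 6 did not pass (8 and 2 adjusted over the list alone) of 15 in Ile. The median was 0.49, with camera adjusted p = 2.24e-09, or adjusted p = 0.0457 with an estimated correlation. With the letters as a block the latter p was 0.0822. Members of a list can move together for reasons other than the treatment, which the preset correlation does not allow for. In 100 splits of all libraries, the real one included, the highest other count at the preset correlation was 170.

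**Figure D2:**
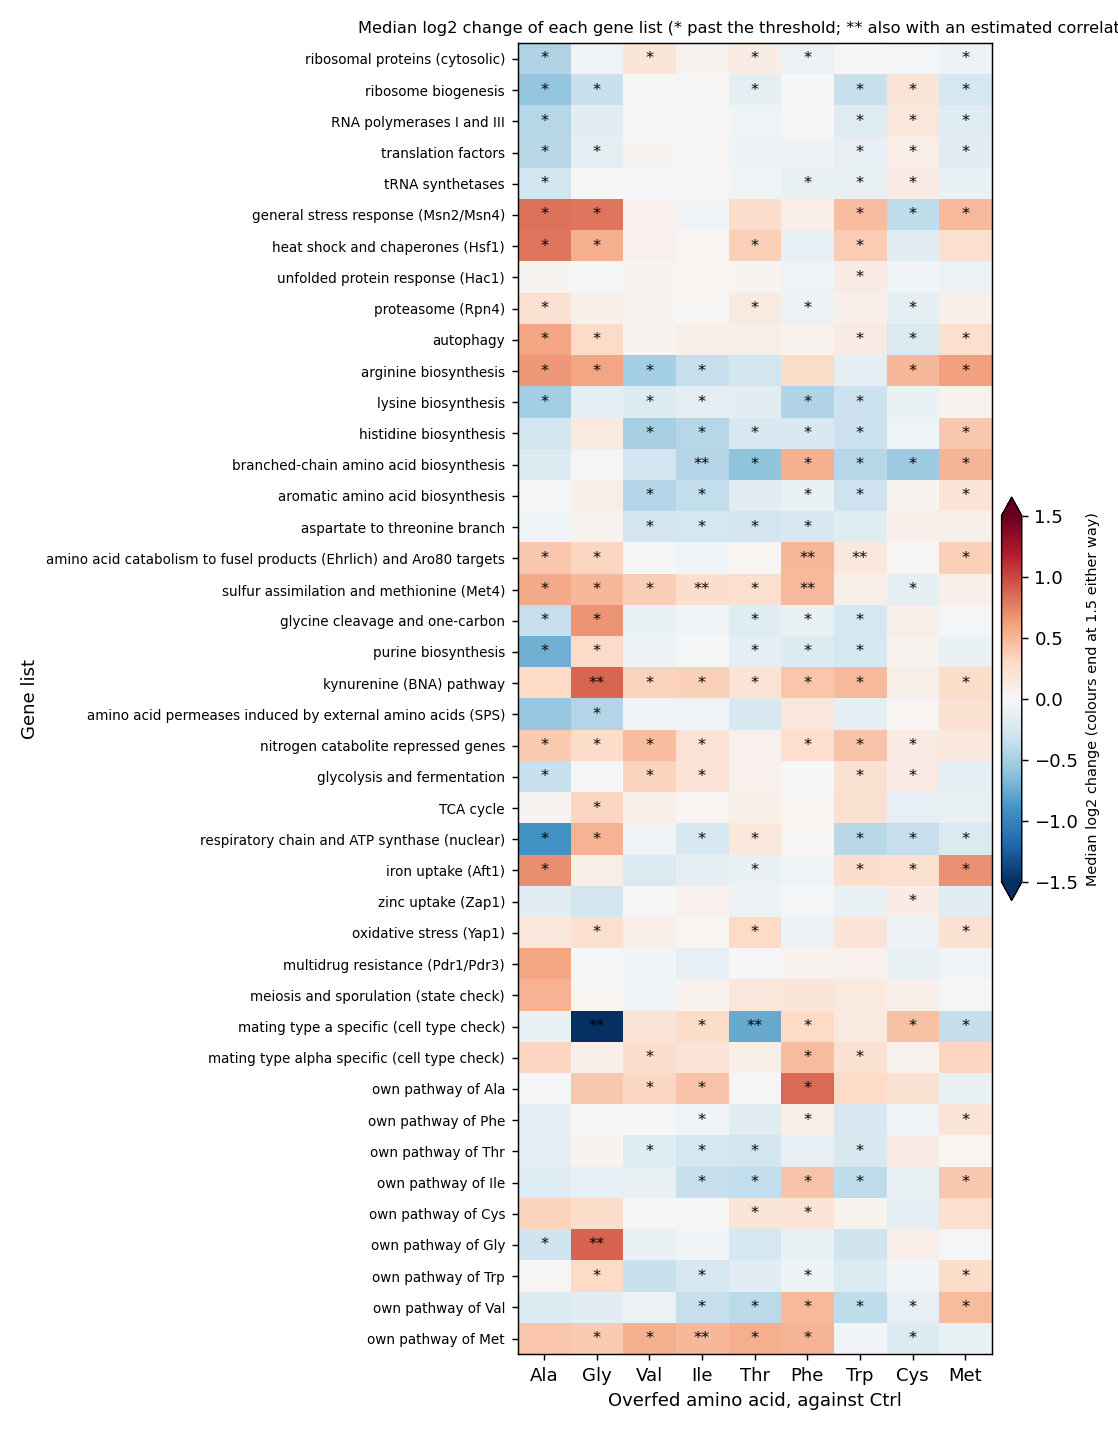
Median log2 fold change against Ctrl of each gene list (vertical) in each amino acid group (horizontal), as colour that ends at 1.5. A star marks a list past the camera threshold and a double star also with an estimated correlation, which 10 of the 378 squares have.

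**Figure D3:**
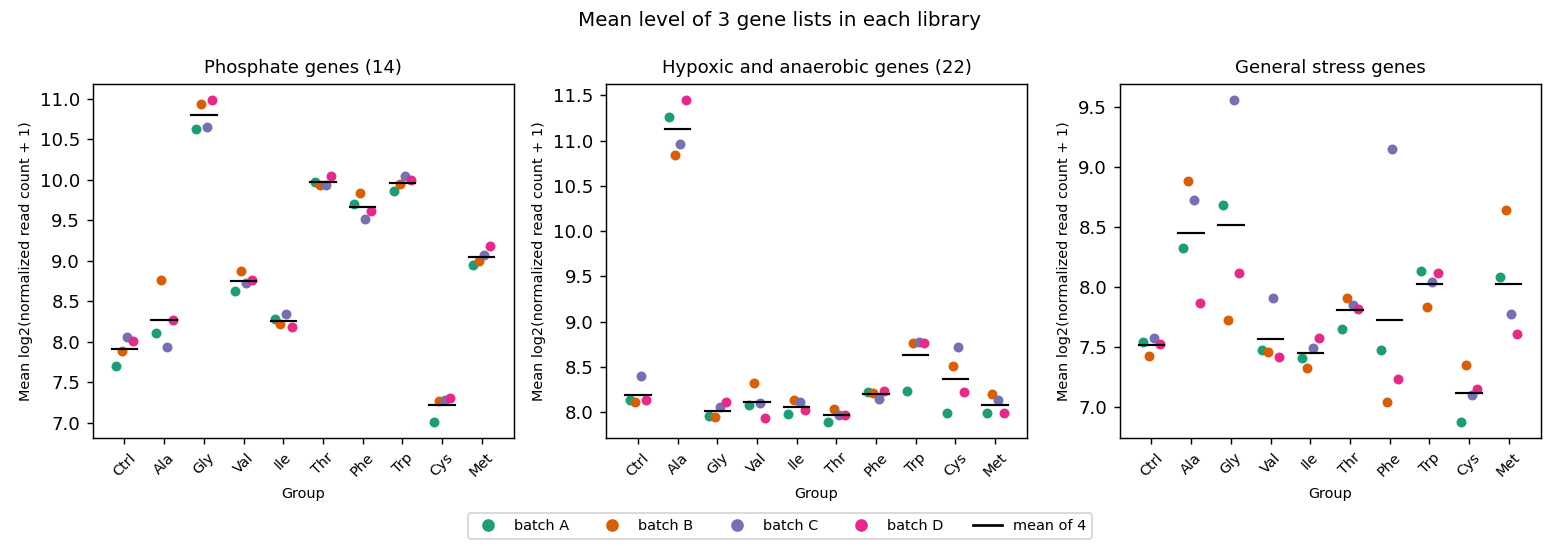
Mean log2 level of the phosphate, hypoxic and general stress lists in each of the 40 libraries, by group, the first 2 lists having been chosen after seeing the data. Ala stands highest in the hypoxic list and Gly in the phosphate list, and Phe replicate C (9.15) and Gly replicate C (9.56) stand above their groups in the stress list.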

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

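All values here come from a check of 329 sets of 4 libraries (50 of library measures, 40 of list means, 239 of gene values) chosen after seeing the data: a library was singled out when its gap to the nearest of the other 3 exceeded, as a share of the whole range, Dixon's critical value for 4 samples. Chance singles out about 1 in 20 groups, here 16.45, and 31 were found. Each ratio given is that share.

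In estimated reads, Ile C (17928611 against 6691937 to 8581888, ratio 0.832) and Cys C (14983392 against 5652035 to 7193140, ratio 0.835) lay above their groups. In the share of small noncoding RNA, Thr A (0.878) and Trp A (0.850) lay above and Cys D (0.911) below. Val C lay below on the second principal component (0.876). Among list means, Val C lay above in the general stress list (0.876), Met B above in the respiratory list (0.862), Ctrl C above in the hypoxic list (8.40 against 8.11 to 8.13 on the log2 scale, ratio 0.923), Trp A below in the hypoxic list (8.23 against 8.76 to 8.78, ratio 0.964) and Cys A below in the phosphate list (0.875).

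Gene values that stood above their group were ROX1 in Ala C (0.877), MHT1 in Ile C (0.850), PHO89 in Phe B (0.949) and Cys D (0.935), ARG8 in Cys D (0.874) and SAM2 in Met C (0.856). Below lay DAN1 in Trp A (0.867) and IRC7 in Cys D (0.958). In Ctrl, TIR1 in B lay below (0.914) and AGX1 in A above (0.867). Ctrl C held the other 10: HXT1 (0.891), STP4 (0.941), ARO5 (8.11 against 9.41 to 9.45, ratio 0.970), ARG7 (0.905) and ARG3 (0.924) were below, and ANB1 (0.911), YHR138C (0.846), ZRT1 (0.836), IRC7 (0.851) and SAM2 (0.970) above. A low or high Ctrl library enters all 9 comparisons, and the calls of these genes that ended without Ctrl C are given beside them in the results.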

How the results depend on the processing

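The alternatives here were chosen before the data were examined, except leaving out Phe replicate C in the results over all groups. Of 733 named gene values, 569 kept their call under every alternative run, 164 lost it under at least 1 (149 when 1 library was left out, 57 in the fit to the compared groups), and none changed sign. Pseudocounts of 0.25 and 4, no filter, and the median of ratios moved none of the 27 main results by over 1.5 times. Equal totals moved 1, genes set apart in Val, to 175. With the letters as a block, genes changed in Val became 499 and genes set apart in Val 177. The block changed 7 list calls: multidrug resistance in Ala (adjusted p 0.0614 to 0.0472) and Ile (0.0699 to 0.0468) and the proteasome in Trp (0.0519 to 0.0413) and Met (0.0690 to 0.0413) passed with it, and the Ehrlich list in Gly (0.0334 to 0.0600), oxidative stress in Thr (0.0498 to 0.0533) and the mating type alpha list in Trp (0.0403 to 0.0530) did not. With an estimated correlation it ended the 3 calls in Ile given above, and it changed no other call.

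The fit to the compared groups alone gave 494 genes in Val, 195 in Phe, 1311 in Trp and 79 in Cys. For the pairs it gave 13 for Ile against Val, 269 for Phe against Trp, 1199 for Ala against Gly and 976 for Met against Cys. It takes the spread from fewer libraries and from the compared groups only, where the main fit pools it over all 10 groups. Counts rose in Val, Trp and Ile against Val and fell in the others. The cause of each move was not tested. Splitting the controls lowered the median correlation to 0.287, and an estimated correlation left 10 list calls. Leaving out 1 library gave 204 to 351 genes in Val, 465 to 681 in Trp, 103 to 175 in Cys and 319 to 564 for the mean of the 9. Genes set apart ranged over 63 to 133 in Val, 33 to 66 in Ile, 102 to 200 in Phe, 142 to 384 in Trp and 86 to 166 in Cys. Pairs ranged over 5 to 9 for Ile against Val, 352 to 1389 for Phe against Trp and 1050.0 to 1630.0 for Met against Cys, and shared genes over 148 to 226. For the other results each value stayed within 1.5 times that with all libraries, among them 2458 to 3046 genes in Ala and 1171 to 1848 in Gly. Without Phe replicate C, 179 list pairs passed, the median correlation was 0.418 and 226 genes were shared. Equal totals changed the sign of 37 list medians, all between -0.16 and 0.17. The edgeR test planned for whole reads was not run, since the share of values that came out whole was 88.8 to 90.9%. Depth may limit the calls of genes with few reads, such as DAN1 in most groups outside Ala, but this was not tested.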

Other observations

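The gene lists and tests in this part, the splits of the samples included, were chosen after the results were seen. Genes of the phosphate regulon, which Pho4 activates when phosphate is short, rose together in most groups. All 14 rose in Gly (median log2 fold change 2.89, camera adjusted p = 1.86e-35, adjusted p = 9.26e-07 with an estimated correlation) and in Thr (2.07, adjusted p = 6.48e-07 with an estimated correlation), 13 in Trp (1.80, 9.26e-07), 11 in Phe (1.36, 6.48e-07), 11 in Met (0.75, 5.62e-04) and 9 in Val (0.72, 0.00162). In Ala 5 rose (0.22, or 0.40 with equal library totals, adjusted p = 0.394 with an estimated correlation) and in Ile 1 (0.23, 0.0902), while in Cys 5 fell and none rose (-0.28, 0.0125). The acid phosphatase PHO5 rose by 3.26 in Gly and 2.54 in Thr, and PHO84 stood at -1.59 in Cys. The mean log2 level of the list was 7.92 ± 0.16 in Ctrl (SD, n = 4), 10.81 ± 0.19 in Gly, 9.97 ± 0.05 in Thr and 7.22 ± 0.14 in Cys.

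Of 22 hypoxic and anaerobic genes, 18 rose in Ala and none fell (1.73, camera adjusted p = 7.67e-19, adjusted p = 0.00197 with an estimated correlation), including the mannoproteins TIR4 (5.43) and TIR3 (4.83) and ANB1 (5.72). Trp gave 7 rises, TIR1 by 2.44 among them, and 1 fall, the fatty acid desaturase OLE1 (-0.91), and the list did not pass with an estimated correlation (adjusted p = 0.409). Among 18 pheromone response genes 10 fell in Gly (-0.57, adjusted p = 0.00107 with an estimated correlation), such as SST2 (-2.22), FAR1 (-1.77) and STE4 (-1.33), and 6 in Thr (-0.27, 0.0325), and none rose in either. Of 7 hexose transporters none rose in any comparison, and falls numbered 3 in Val (median -0.68, adjusted p = 0.0164 with an estimated correlation), 3 in Thr (-0.97, 0.0247), 4 in Trp (-0.61, 0.0506), 4 in Ala (-0.88, 0.274), 2 in Phe (-0.38, 0.148), 2 in Gly (-0.44, 0.351), and 1 each in Ile (-0.53, 0.0506), Cys (-0.19, 0.189) and Met (-0.55, 0.409). In ergosterol synthesis 13 of 23 rose and 5 fell in Ala, ERG27 at 1.14 and ERG5 at -1.48 (0.39, camera adjusted p = 0.0122, adjusted p = 0.274 with an estimated correlation).

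A candidate explanation of the hypoxic genes in Ala is less oxygen or heme in those cultures, a hypothesis. Scaling of the libraries is argued against, as the list's median was at least 1.73 under the 3 scalings while scaling moved the median of all genes by 0.187, and so are single libraries, as the 4 letters gave medians of 1.54 to 2.23. Glucose used up at a later growth stage, with oxygen unchanged, would raise respiratory genes. Their median was -0.91, with 28 of 34 fallen and 0 risen. A later stage that also had less oxygen is not covered by this. That same -0.91 is what less oxygen or heme would give, in a test made on data already seen. How dense or aerated the cultures were is not stated in the labels, so this stays open.

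For the phosphate genes, single low control libraries are argued against, as 7 of the 9 groups had all 4 libraries above the highest Ctrl library, and a Ctrl group low as a whole cannot give the differences among the 9 groups (7.22 ± 0.14 in Cys to 10.81 ± 0.19 in Gly), though its part in the smaller rises stays open. Batch letters would give the rise in some letters only, whereas 7 to 8 of the 9 groups lay above Ctrl within each letter. A stress state of single cultures is argued against: within groups the phosphate list moved by -0.0945 ± 0.0627 (SE, 40 libraries, -0.0847 with the letters also removed) per log2 unit of the stress list, against 1.62 over the 10 group means, and Phe C had the highest stress (9.15) and lowest phosphate level (9.52) of its group. A stress state shared by a whole group stays open. Of 45 pairs of groups 36 had the same order in both lists. Of these 15, against 0 of opposite order, passed in both (exact permutation p under 0.05, two-sided, unadjusted). Other values went the other way. Phe A, B and D had phosphate levels of 9.62 to 9.84 with stress levels of 7.04 to 7.47, near Ctrl. Ala had a stress level of 8.45 ± 0.45 and a phosphate level of 8.27 ± 0.36, where Gly had 8.52 ± 0.80 and 10.81 ± 0.19. Ala minus Thr was 0.645 in the stress list (exact permutation p = 0.0571) and -1.70 in the phosphate list (exact permutation p = 0.0286). Phosphate was not measured, and no biological explanation was tested.

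Phe replicate C stood apart in the stress list by 1.90 from the mean of the other Phe libraries, with HSP12 at 7353 against 856, though its gap of 0.797 of the range fell short of the Dixon limit used above. A mislabelled library is argued against, since ARO9 there was 31.5 times the highest of the 32 libraries outside Phe and Trp (15520.3 against 493), and LEU1 was 41930.4, near the 48357 of the other Phe libraries and far from the 10747 of Trp. Sequencing depth is argued against too: the 8 deepest of the other libraries deviated by a median of 0.055 (-0.26 to 1.39, the last in Gly C). Most of these carried the letter C, so depth and letter were not separated here. No biological explanation was tested, since the labels set this library apart by its letter alone.

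In other splits of the 8 libraries of each of the 14 comparisons, the real split alone gave as many genes, 1 of 35 each time, the smallest share these splits can give. With the letters disregarded this share lay under 0.05 for each comparison taken singly. The letters pair the libraries, and the splits that keep the pairs, given below, are too few to exclude chance. The real count and the highest of the others were 2881 and 1214 in Ala, 1597 and 126 in Gly, 329 and 0 in Val, 117 and 38 in Ile, 683 and 3 in Thr, 342 and 12 in Phe, 752 and 0 in Trp, 173 and 62 in Cys, and 598 and 26 in Met. For the pairs they were 8 and 1 (Ile and Val), 726 and 687 (Phe and Trp), 1882 and 1228 (Ala and Gly), 1624 and 926 (Met and Cys) and 400 and 1 (Thr and Val). Since the letters pair the libraries, the real split was also set against those that part all 4 letters, which are 8 and too few for a share under 0.05. The highest others among them were 625 in Ala, 6 in Gly, 8 in Phe, 687 for Phe and Trp, 568 for Ala and Gly, 74 for Met and Cys, 1 for Ile and Val, and 0 in the rest. The 687 came from exchanging the C libraries of Phe and Trp, so that pair's count was nearly as high with these exchanged. Both moved at once, so this cannot be put down to Phe replicate C alone, without which the count was 1389.

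For genes set apart, 100 splits of the amino acid libraries were made, the real one included, with the Ctrl libraries left in place. Of these 1 gave as many genes as seen in Ala (2477, highest other 1902), Gly (1055, 617), Thr (351, 125), Phe (162, 0), Cys (144, 0) and Met (334, 23). For these 6 the share of splits lay under 0.05, each taken singly and with the letters disregarded. As many came from 3 in Val (113, 259), 2 in Ile (54, 1217) and 3 in Trp (295, 672). In these 3, other splits lay above the real count, far above it in Ile. As the letters were disregarded throughout, chance is not called excluded for any of the 9. Why some splits gave so many genes was not tested. In 100 splits of all libraries, Ctrl included, the mean of the 9 (551, 527), shared genes (224, 1) and list calls (178, 170) were each reached by 1. That was the real one, but for the mean of the 9 and the list calls another split came near it. The median correlation of fold changes, 0.455, was reached or passed by 75 of 100 (highest 0.732). The comparisons share the Ctrl libraries, which alone gave 0.501 in simulation with no effect. These splits therefore cannot tell the correlation from chance in either direction.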
